A study of Homo sapiens with 15 samples.

How the data were processed

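ChIP-seq was measured in TF-1, a human erythroleukemia cell line, carrying an inducible vector for either wild-type (WT) RAD21 or RAD21 Q592*, a form with a premature stop codon. Per the labels' protocols, expression was induced with doxycycline for 6 days. Chromatin was fixed in 1% formaldehyde for 10 minutes and sheared to fragments of 200 to 400 bp on average. ChIP was done with an antibody to GATA2, RUNX1 or SMC3. The 15 samples are 11 ChIP libraries and 4 input libraries. Each line has 2 libraries per target and 2 inputs by its labels, except that Q592* RUNX1 has 1 library.

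The files hold 6 lists of peaks, 1 for each line and target, and their peak names carry the word merge, so each list was taken as 1 pooled call over the libraries of its group. No list holds a value per library. Per the submitters' processing notes, Bowtie2, Picard, MACS2 and the genome build hg19 were used; their versions and settings are not given in the sources used here. The deposited fold enrichment of a peak is the ratio of the ChIP pileup at its summit to the local background that MACS2 estimated. The deposited −log10 p-value and −log10 q-value are those of the same summit. The deposited score is 10 times the −log10 q, cut to a whole number, and was not used. These values per peak are the authors' own and served to describe, rank or filter peaks within their list. Counts of peaks above a common −log10 q are compared between lists, although that value also depends on the size of the background pool. The recovered quantities described next are a further exception. The report compares the totals of the lists and gives the local background of the 5 strongest WT-only GATA2 and RUNX1 regions. Comparisons of recovered values per peak between lists are confined to the closing section, apart from counts at a coverage threshold. The lowest −log10 q of a list lay between 2.00 and 2.05, so weaker peaks cannot be seen. All peaks lay on chromosomes 1 to 22, X and Y. Coordinates are those of hg19, counted from 1.

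The depth of each pool was recovered from the peak values, since MACS2 computes the fold and the p from a whole number of ChIP reads and a Poisson background. The genome-wide background of a list and the worth of 1 ChIP read on the scale of the background were fitted. This background was the value that accounted for the largest number of peaks, though a minority of each list (8870 of 38962 for WT GATA2, 1142 of 15582 for Q592* RUNX1). They gave a whole number of reads for 100% of the peaks of each list to within 0.002 of the deposited −log10 p, against at most 1.35% when the worth of a read was set wrong by 3%. The totals further assume the preset effective genome size of 2700000000 bp and a fragment length equal to the narrowest peak of the list, and depend on both. The background totals differ between lists of a line although each line has 2 inputs by its labels, so which inputs entered each list is not known. They are given in M reads, M standing for 1000000. On simulated peaks made with known totals, at least 99.99% of the summit pileups came back exact in each of the 6 simulated lists.

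The lists of both lines were joined per target. Peaks that overlapped by at least 1 bp formed a region, and a region was called shared, Q592*-only or WT-only by the lists with a peak in it. Co-occupancy is the percentage of the peaks of one target that overlap a peak of another target in the same line. Chance overlap was measured by moving each chromosome of one list by a random distance, 100 times. Percentages carry 95% Wilson intervals, which cover counting error only. Because each line has 1 pooled list per target, no test between the lines was possible and none is given. Standard errors (SE) come from resampling regions, or from counts within bins of strength, in these pooled lists. They cover the spread between regions or counting error, and not the variation between libraries or lines. The overlap functions, the random shifts, the rescaling to another depth and the matching on peak strength were tested on simulated data. With no loss simulated for 40000 peaks, matching on strength brought a raw difference of 19.6 percentage points down to 0.8, and with a true loss of 14.7 points it gave 16.0. The strength of these simulated peaks carried no noise. Scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

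The regions named by position follow a rule fixed before the data were examined: the 5 Q592*-only and the 5 WT-only regions of each target with the highest −log10 q in their own list, of which the text prints part. The rule also covered genes, and 12 gene lists, a promoter share and a motif share had been planned. These need the annotation or the sequence of hg19, which were not used here, so no gene is assigned to a region. Alternatives planned before the data were examined were a −log10 q of at least 10, equal list lengths, a reciprocal overlap of 50%, summits within 200 bp and every contig. Added later were a threshold of 10 times the mean ChIP coverage of a list, the omission of chromosomes 13, 20 and Y, and all alternatives of the GATA2 share of SMC3 regions.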

Results

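The series asks how the binding of GATA2, RUNX1 and cohesin on chromatin differs between TF-1 erythroleukemia cells that express mutant RAD21 and those that express the wild-type protein. RAD21 and SMC3 are subunits of cohesin, the ring-shaped complex that holds sister chromatids together and shapes chromatin loops. GATA2 and RUNX1 are transcription factors of blood stem and progenitor cells. Each of the 6 groups of ChIP libraries is represented by 1 pooled peak list, so there is no replicate spread and each difference between the lines is a difference between 2 pooled lists. The 2 lines were sequenced to similar depth by the totals recovered from the peak values. These were 106 (GATA2), 107 (RUNX1) and 93.5 M ChIP reads (SMC3) for Q592* and 108, 105 and 103.5 M for WT. The background pools were smaller in Q592*, at 78.0, 78.0 and 72.6 M reads, than in WT, at 95.3, 86.7 and 86.7 M.

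GATA2 was called at many more places in the cells with mutant RAD21. The Q592* list held 59009 GATA2 peaks and the WT list 38962, a ratio of 1.51. Most WT peaks were also present in Q592*: 33867 of 38962 (86.9%, 95% interval 86.6 to 87.2%) overlapped a Q592* peak, against 1.30% on average after random shifts. In the other direction only 56.5% (56.1 to 56.9%) of the Q592* peaks overlapped a WT peak. Joined, the lists gave 33241 shared regions, 25653 Q592*-only regions and 5095 WT-only regions, so the regions of Q592* alone outnumbered those of WT alone by a ratio of 5.04.

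The additional GATA2 regions of Q592* were mostly weak by the authors' values, but not all of them were. Peaks of the Q592* list without a WT partner had a median −log10 q of 8.75, and those with one had 30.6. Of the weakest quartile of Q592* peaks 20.8% had a WT partner, and of the strongest quartile 97.2%. The ratio between the lists was larger at a high −log10 q: with at least 100, 5458 peaks remained in Q592* and 1697 in WT, a ratio of 3.22. With both lists trimmed to the same length, 10215 Q592*-only and 9655 WT-only GATA2 regions were found, and the excess disappeared, since equal lengths leave nearly equal remainders by construction.

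The strongest Q592*-only GATA2 region lay on chromosome 1 from 156864801 to 156865326, with a fold enrichment of 12.1 and a −log10 q of 139.5. The next were on chromosome 6 from 134496112 to 134496386 (fold 9.90), where SMC3 was also called in Q592*, and on chromosome 7 from 5631124 to 5631458 (fold 12.1), where RUNX1 was called in both lines. The fourth-ranked region, on chromosome 2 from 26991873 to 26992165 (fold 8.17), also carried RUNX1 in both lines. The 5 strongest WT-only GATA2 regions had folds of 2.49 to 4.85 and were also called for RUNX1 and for SMC3 in WT. They lay on chromosome Y (58836567 to 58836818 and 58883522 to 58883921), on chromosome 16 (46392970 to 46393389 and 46407585 to 46407840) and on chromosome 4 (49512229 to 49512677). Their local background was 6.99 to 26.1 times the value that applied genome-wide.

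**Figure D1:**
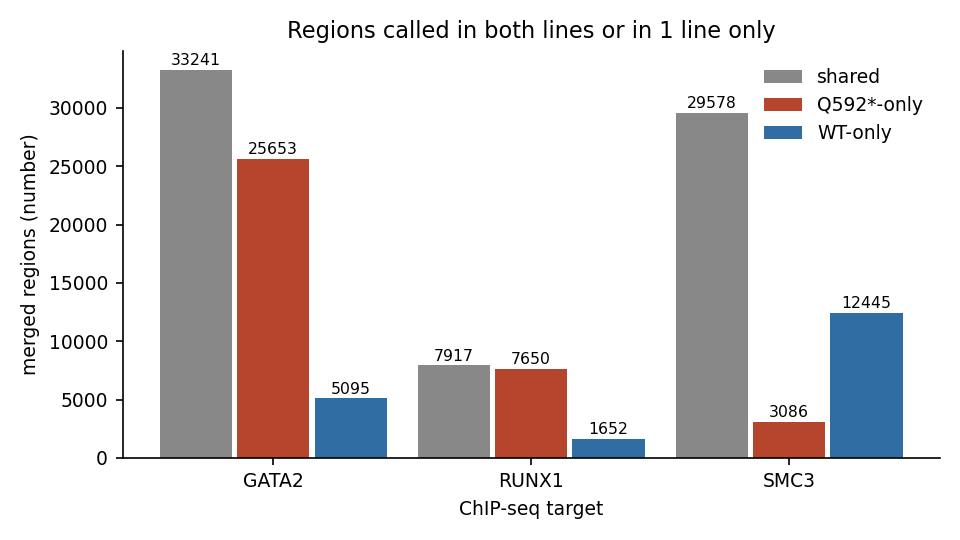
Bars give the number of merged regions (vertical axis) for GATA2, RUNX1 and SMC3, split into regions called in both lines (grey), in Q592* only (red) and in WT only (blue). Q592*-only regions outnumber WT-only regions for GATA2 (25653 and 5095) and RUNX1 (7650 and 1652), and the order is the opposite for SMC3 (3086 and 12445).

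RUNX1 followed the same direction as GATA2, with fewer peaks but a larger ratio. The Q592* list held 15582 RUNX1 peaks and the WT list 9603, a ratio of 1.62, although 1 library is labelled for Q592* and 2 for WT. Of the WT peaks 82.8% (82.0 to 83.5%) overlapped a Q592* peak, against 0.27% after random shifts, and of the Q592* peaks 50.9% (50.1 to 51.7%) overlapped a WT peak. There were 7917 shared, 7650 Q592*-only and 1652 WT-only regions. At a −log10 q of at least 100 the counts were 573 peaks in Q592* and 81 in WT. Trimming both lists to 9603 peaks left 3114 Q592*-only and 3088 WT-only regions.

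The strongest Q592*-only RUNX1 region was on chromosome 6 from 17600395 to 17600746, with a fold enrichment of 10.6 and a −log10 q of 95.9, and no other target was called there in either line. It was followed by a region on chromosome 19 from 16999482 to 16999940 (fold 5.36), also called for GATA2 in Q592*, and by one on chromosome 10 from 73508561 to 73508890 (fold 6.30), also called for SMC3 in Q592*. The strongest WT-only RUNX1 region, on chromosome Y from 58836580 to 58836808 (fold 4.69), overlapped the strongest WT-only GATA2 region. All 5 of the strongest WT-only RUNX1 regions were also GATA2 and SMC3 peaks in WT. They lay on chromosomes Y, 16 and 10. Their local background, highest first, was 8.42, 7.17, 6.12, 6.05 and 1.12 times the value that applied genome-wide. Places called under any antibody were not filtered out, so these calls need not reflect binding of the 3 targets.

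SMC3 went the other way. The Q592* list held 32789 SMC3 peaks and the WT list 42353, which is 22.6% fewer in the mutant line. Most Q592* peaks had a WT partner (90.6%, 90.3 to 90.9%), whereas 70.6% (70.2 to 71.1%) of the WT peaks had a Q592* partner. There were 29578 shared, 3086 Q592*-only and 12445 WT-only regions. WT peaks without a Q592* partner came from the weak part of the list: 24.0% of its weakest quartile had a Q592* partner, 61.7% of the next, 96.8% of the next and 100% of the strongest. WT peaks without a partner had a median −log10 q of 6.25, against 33.6 for those with one. The SMC3 lists also differed at a high −log10 q. At a value of at least 100 there were 2870 peaks in Q592* and 3865 in WT, a ratio of 0.743. The ratio was 0.774 for the full lists and 0.912 at a −log10 q of at least 20. The −log10 q also depends on the background pool, at 72.6 M reads in Q592* and 86.7 M in WT. Equal values therefore need not mean equal strength in the 2 lists. At the threshold on ChIP coverage, added later, 23098 SMC3 peaks remained in Q592* and 25478 in WT. With equal list lengths 5109 Q592*-only and 5055 WT-only SMC3 regions remained.

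The strongest WT-only SMC3 region was on chromosome 11 from 108288311 to 108288604, with a fold enrichment of 12.6 and a −log10 q of 48.9. It was followed by regions on chromosome 3 from 42613861 to 42614130 (fold 7.55) and on chromosome Y from 58836599 to 58836788 (fold 4.73). The first pair carried no GATA2 or RUNX1 peak in either line, and the region on Y was the high-background place already named. The strongest Q592*-only SMC3 regions were on chromosome 2 from 27308409 to 27308670 (fold 5.63) and on chromosome 22 from 39795587 to 39795782 (fold 5.36), and no other target was called at either.

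**Figure D2:**
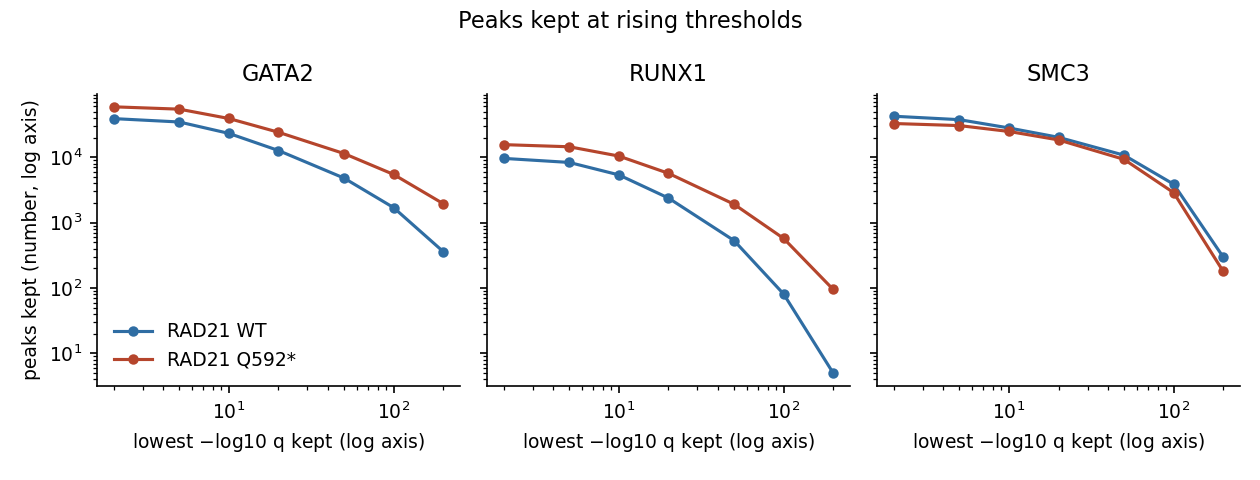
Points give the number of peaks kept (vertical log axis) at each lowest −log10 q (horizontal log axis) for the WT (blue) and Q592* (red) lists of each target. The Q592* list stays above the WT list for GATA2 and RUNX1, and the WT list stays above the Q592* list for SMC3, with 28044 and 24790 peaks at a −log10 q of at least 10.

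The direction held across chromosomes for each target. GATA2 had more peaks in Q592* on 24 of 24 chromosomes, with ratios of Q592* to WT from 1.08 (Y) to 1.89 (X). RUNX1 had more on 23 of 24, with the exception of Y at 0.96. SMC3 had fewer in Q592* on every one of the 24 chromosomes, with ratios from 0.53 (Y) to 0.91 (19).

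A segment of chromosome 13 departed from this rule for GATA2 and RUNX1. Between 75 and 100 Mb, 546 of the GATA2 regions were WT-only and 428 Q592*-only; the WT-only ones made up 33.2% of the GATA2 regions there, compared with 4.47% on the rest of the chromosome and 7.36% on the other chromosomes. For RUNX1 189 regions of the segment were WT-only (47.5%, compared with 5.56% and 8.76%) and 82 Q592*-only. SMC3 kept its direction there, with 329 WT-only regions (49.6%, compared with 27.01% and 27.3%) and 65 Q592*-only ones. The segment thus held 10.7% of all WT-only GATA2 regions and 11.4% of all WT-only RUNX1 regions. In the windows from 85 to 90 Mb and from 90 to 95 Mb, 190 and 204 GATA2 regions were WT-only and 111 and 87 were Q592*-only. The other windows of the segment kept the usual direction for GATA2, with 105, 67 and 58 Q592*-only and 87, 45 and 20 WT-only regions. RUNX1 kept it from 75 to 80 Mb (21 Q592*-only and 19 WT-only) and from 95 to 100 Mb (19 and 6). The segment was chosen after its counts had been seen. It was not the only place that departed. Among 5 Mb windows with at least 20 shared regions, WT-only regions outnumbered Q592*-only ones in 3 of 504 for GATA2 and 6 of 128 for RUNX1. Some of these windows lay on other chromosomes.

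**Figure D3:**
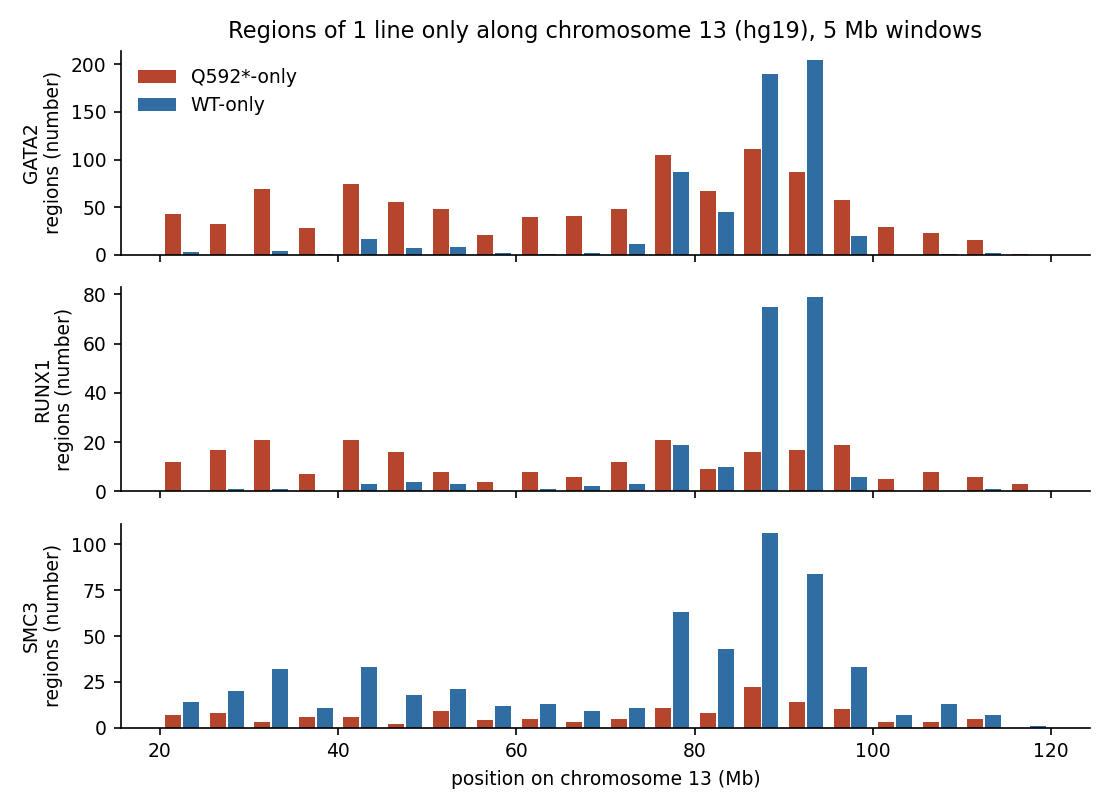
Bars give the number of Q592*-only (red) and WT-only (blue) regions in 5 Mb windows along chromosome 13 (horizontal axis, Mb, hg19) for GATA2, RUNX1 and SMC3 from top to bottom. WT-only regions of all 3 targets pile up between 85 and 95 Mb, where GATA2 has 190 and 204 of them per window.

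GATA2 and RUNX1 were found together to a similar extent in both lines. Of the RUNX1 peaks 75.02% (74.1 to 75.9%) overlapped a GATA2 peak in WT and 74.9% (74.2 to 75.6%) in Q592*, and random shifts gave 0.74% and 1.19%. Of the GATA2 peaks 18.3% (17.9 to 18.7%) overlapped a RUNX1 peak in WT and 19.5% (19.2 to 19.8%) in Q592*. Shared GATA2 regions carried RUNX1 of the same line more often than GATA2 regions of that line alone. The values were 29.0% and 7.24% in Q592* and 20.5% and 6.28% in WT. GATA2 peaks without a partner in the other line were weaker in both lines, and these shares were not matched on strength.

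By the full lists, SMC3 was found at fewer GATA2 and RUNX1 peaks in the mutant line. It overlapped 10256 of 38962 GATA2 peaks in WT (26.3%, 25.9 to 26.8%) and 6888 of 59009 in Q592* (11.7%, 11.4 to 11.9%). It overlapped 49.2% (48.2 to 50.2%) of the RUNX1 peaks in WT and 25.1% (24.4 to 25.8%) in Q592*. Random shifts gave at most 1.09% in these 4 comparisons. The gap depended on list length. With lists of equal length per target nearly all of it was gone: SMC3 overlapped 15.1% of the GATA2 peaks in WT and 14.7% in Q592*, and 30.7% and 28.9% of the RUNX1 peaks. At a −log10 q of at least 10 in all lists it stayed, and the GATA2 values were 13.4% in WT and 6.39% in Q592*.

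In both lines, SMC3 regions of that line alone lay at transcription factor peaks more often than the shared ones. Of the 12445 WT-only SMC3 regions 46.2% (45.3 to 47.1%) overlapped a WT GATA2 peak, compared with 16.0% (15.6 to 16.5%) of the 29578 shared SMC3 regions. For WT RUNX1 peaks the values were 18.8% (18.1 to 19.5%) and 8.16% (7.86 to 8.48%). Of the 3086 Q592*-only SMC3 regions 31.7% (30.04 to 33.3%) overlapped a Q592* GATA2 peak and 18.05% (16.7 to 19.45%) a Q592* RUNX1 peak, compared with 20.25% (19.8 to 20.7%) and 11.4% (11.0 to 11.7%) of the shared ones. GATA2 was called in Q592* at 48.0% (47.1 to 48.9%) of the WT-only SMC3 regions and RUNX1 at 20.8% (20.1 to 21.5%). Counted the other way, 9656 of the 33241 shared GATA2 regions carried SMC3 in WT (29.0%) and 5278 in Q592* (15.9%). WT SMC3 peaks at GATA2 peaks were weaker, with a median −log10 q of 7.88, than those elsewhere, with 26.6.

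**Figure D4:**
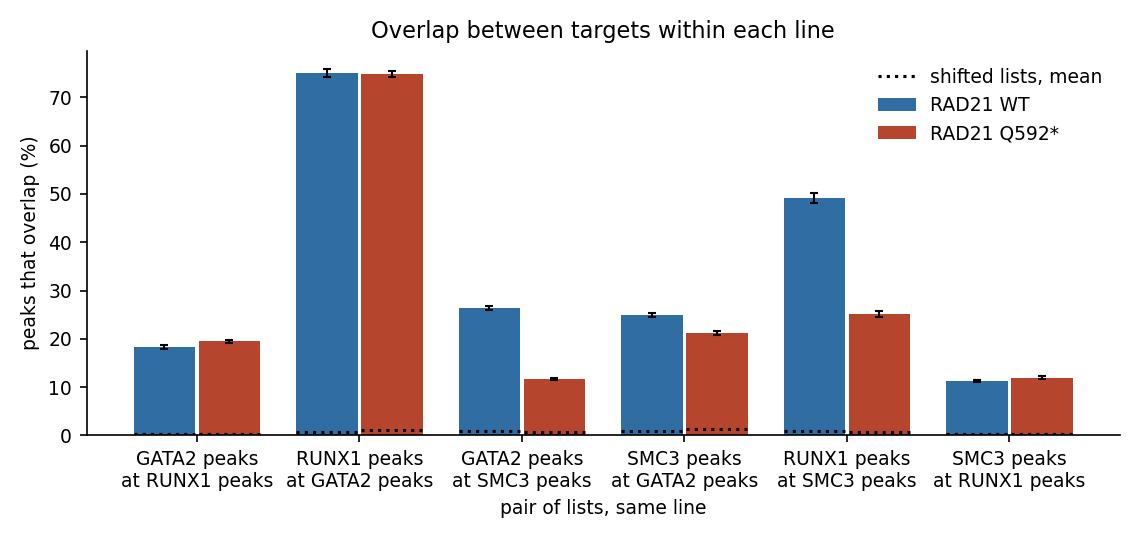
Bars give the percentage of the peaks of one target (vertical axis) that overlap a peak of another target in the same line, WT in blue and Q592* in red, with 95% Wilson intervals; dotted lines give the mean after random shifts. The pair of RUNX1 peaks at GATA2 peaks is level at 75.02% and 74.9%, while GATA2 peaks at SMC3 peaks stand at 26.3% and 11.7%.

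By the full lists, places that carried all 3 targets were fewer in Q592* while places with GATA2 and RUNX1 but no SMC3 were more numerous. In Q592* these lists were longer for GATA2 and RUNX1 and shorter for SMC3, which by itself moves the counts this way. The counts were not repeated with lists of equal length, at which the gap in SMC3 overlap was nearly gone. WT had 4194 regions with all 3 targets and Q592* had 3373. Regions with GATA2 and RUNX1 alone numbered 2934 in WT and 8129 in Q592*, and those with GATA2 and SMC3 alone 6007 and 3468. Regions with SMC3 alone made up 43.1% of the 72535 regions of WT and 28.7% of the 88106 regions of Q592*.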

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

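The tests of sequencing depth were fixed before their results were seen; the test of 1 common enrichment factor was chosen after the result it concerns was seen, and its comparison was moved from the weakest to the second-weakest quartile once both values were known. What drew attention is that the targets moved in opposite directions between the same lines. The log2 ratio of list size, Q592* over WT, was 0.60 for GATA2, 0.70 for RUNX1 and -0.37 for SMC3. With 1 pooled list per target and line this difference was not tested.

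The recovered totals argue against depth and the size of the background pool as the whole account. Q592* had 0.985 (GATA2) and 1.019 (RUNX1) times the ChIP total of WT and 0.818 and 0.899 times its background total, with longer lists. Totals cannot address the local make-up of the background pools, which was not tested as a cause. With totals this close, rescaling to WT could hardly lose a peak and adds little (59009 of 59009 GATA2 and 15569 of 15582 RUNX1 peaks stayed), whereas for SMC3, where Q592* had 0.903 times the ChIP total, 41510 of the 42353 WT peaks stayed at the totals of Q592*, whose list holds 32789. Summit pileup per M reads at shared regions was higher in Q592* for GATA2 and RUNX1, with a median log2 ratio of 0.80 and 0.65. The assumed fragment lengths were longer in Q592* by 0.066 and 0.041 on the log2 scale. For SMC3 the median log2 ratio was 0.12 (higher at 67.5% of regions). The assumed SMC3 fragment was longer in Q592* by 0.26, which is more than this, so the direction for SMC3 is not settled. A ChIP that enriched every GATA2 region by 1 common factor stays open: the log2 ratio of background-subtracted pileup rose from 0.61 in the weakest quartile to 1.05 in the strongest, a difference of 0.44, but the WT threshold selects the weakest regions, and without that quartile the difference was 0.20 (SE 0.008), above the 0.1 that a common factor was taken to allow, though not beyond the 0.2 set to exclude it, and the threshold may act on that quartile too. Also open, and untested, are the RAD21 form itself and other differences in ChIP efficiency, because each line has 1 pooled list per target; for RUNX1 the single Q592* library adds to this.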

How the results depend on the processing

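The coverage threshold, the omission of chromosomes 13, 20 and Y and every alternative for the GATA2 share of SMC3 regions were chosen after the results were seen; the others were planned. No paired analysis was possible because the peak lists are pooled over libraries and carry no replicate numbers, which also rules out leaving out a library. What had been planned for promoters, motifs and gene lists was not run, since it needs hg19 annotation or sequence. Of 63 alternative region counts 42 stayed within 1.5 times the reported count, including all with every contig (the lists hold no other contigs), all without chromosomes 13, 20 and Y and all with summits within 200 bp. Q592*-only regions stayed more numerous than WT-only regions for GATA2 and RUNX1, and fewer for SMC3, under all alternatives, except that with equal list lengths SMC3 had slightly more Q592*-only regions; equal lengths nearly force equal remainders. The cause of other changes was not tested. Weak peaks and those below the lists' thresholds limit all counts.

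A −log10 q of at least 10 gave 21482 shared and 1448 WT-only GATA2 regions, 4820 and 539 for RUNX1, and 1937 Q592*-only and 5119 WT-only SMC3 regions. RUNX1 was then at 16.6% (WT) and 19.1% (Q592*) of GATA2 peaks, SMC3 at 13.4% and 6.39% of GATA2 peaks and at 25.4% and 11.5% of RUNX1 peaks; GATA2 was at 32.8% of WT-only and 6.37% of shared SMC3 regions. Equal list lengths gave 10215 Q592*-only and 9655 WT-only regions for GATA2, 3114 and 3088 for RUNX1, and 5109 and 5055 for SMC3. RUNX1 was then at 17.8% of Q592* GATA2 peaks, SMC3 at 15.1% (WT) and 14.7% (Q592*) of GATA2 peaks and at 30.7% and 28.9% of RUNX1 peaks; GATA2 was at 42.1% of WT-only and 13.7% of shared SMC3 regions. The coverage threshold gave 13630 shared, 16019 Q592*-only and 220 WT-only GATA2 regions, 3965 shared and 185 WT-only RUNX1 regions, and 1576 Q592*-only and 3890 WT-only SMC3 regions. RUNX1 was then at 19.8% (WT) and 22.7% (Q592*) of GATA2 peaks, SMC3 at 17.0% and 8.51% of GATA2 peaks and at 29.7% and 15.8% of RUNX1 peaks; GATA2 was at 24.2% of WT-only and 6.79% of shared SMC3 regions. Reciprocal overlap gave 9363 WT-only GATA2 and 5026 Q592*-only SMC3 peaks. With summits within 200 bp RUNX1 was at 17.6% (WT) and 18.7% (Q592*) of GATA2 peaks, SMC3 at 24.0% and 10.3% of GATA2 peaks and at 45.5% and 22.9% of RUNX1 peaks; GATA2 was at 41.9% of WT-only and 13.9% of shared SMC3 regions.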

Other observations

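The tests of explanations below were fixed before their own results were seen, apart from the following. The background test on chromosome 19 was added after the background of 20q was known. The copy number explanations were narrowed from a difference to a lower copy number after their results, under the same bounds. The pileup test on chromosome 19 was chosen after its values were seen. A bound of 2 SE above 0 was tried first, under which the bias would count as excluded for these regions. It was replaced by the bound of 0.1 taken from the background test. The chromosome segments and the SMC3 pattern themselves were picked from the data. The distances to shared regions were chosen after the main counts were known. GATA2 and RUNX1 regions of 1 line overlapped each other more often than those of opposite lines. Of the 1652 WT-only RUNX1 regions 14.8% overlapped a WT-only GATA2 region and 4.24% a Q592*-only one. Of the 7650 Q592*-only RUNX1 regions 16.4% overlapped a Q592*-only GATA2 region and 0.44% a WT-only one. Random shifts gave at most 0.375% on average in these 4 comparisons. Of the WT-only RUNX1 regions 28.0% overlapped a WT-only SMC3 region and 0.61% a Q592*-only one (0.186% and 0.037% after random shifts). Of the Q592*-only RUNX1 regions 9.28% overlapped a WT-only SMC3 region and 3.83% a Q592*-only one (0.174% and 0.045% after shifts), and of the Q592*-only GATA2 regions 2.42% and 0.87% (0.192% and 0.047%), where the WT-only SMC3 class is the larger, with 12445 regions against 3086. Most Q592*-only RUNX1 regions with GATA2 lay at GATA2 regions that both lines share (48.0% of all Q592*-only RUNX1 regions). The 13q segment held 10.7% of the WT-only GATA2 and 11.4% of the WT-only RUNX1 regions. The local background, compared at 175 places, was more alike between lists of 1 line (Spearman 0.97 to 0.977) than between lines (0.816 to 0.867). How much of the overlap within a line follows from such places or from a shared background was not tested.

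Regions of 1 line often lay close to shared regions of the same target. Within 10 kb of a shared region lay 42.6% (42.0 to 43.2%) of the Q592*-only GATA2 regions and 54.3% (52.9 to 55.7%) of the WT-only ones, against 17.0% and 17.6% after random shifts. For RUNX1 the values were 15.9% and 22.5%, against 4.96% and 5.12%. For SMC3 they were 40.3% in Q592* and 37.9% in WT, against 17.0% in both.

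The GATA2 share of WT-only SMC3 regions, 46.2% compared with 16.0% in shared regions (in Q592*, 31.7% of Q592*-only and 20.25% of shared SMC3 regions), could follow from peak strength, since SMC3 peaks at GATA2 peaks are the weaker ones. Without matching, 79.0% of the WT SMC3 peaks away from GATA2 had a Q592* partner and 45.4% of those at GATA2, a gap of 33.5 percentage points; within 20 bins of −log10 q with equal numbers of peaks the gap was 5.2 points (SE 0.53), above 0 in 13 bins and up to 13.4 points, but -2.72 and -0.50 in the weakest pair of bins and 0 in the 5 strongest bins, where 100% of both groups had a partner. Matching on strength thus removed most of the gap. The rest was just above the 5 points set beforehand as allowed by strength alone, and under the 10 points set to exclude it. A simulation without loss left 0.8 points (SE 0.53). Its peaks had no noise in their strength, so it cannot show how large a rest such noise leaves. A loss specific to GATA2 sites and strength that the bins do not capture both stay open. GATA2 reads mixed into the WT SMC3 pool are argued against as the whole account, since they would mark strong GATA2 peaks. Of the GATA2 peaks at WT-only SMC3 regions 27.2% (26.1 to 28.4%) ranked below the median of their list. The share of GATA2 peaks at such regions rose with GATA2 strength, from 6.52% in the weakest quartile over 9.25% and 15.2% to 26.98%, as mixing would have it. The share at any WT SMC3 peak rose too (11.5%, 15.2%, 24.1% and 54.5%). That share includes the same regions and comes from the same pool, so it cannot weigh against mixing. A part played by mixing thus stays open. A loss of weakly held cohesin from transcription factor sites under mutant RAD21 stays open as a hypothesis, with no test in these pooled lists.

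A lower copy number of the 13q segment in the Q592* line is argued against by the background. Background ratios here and below come from shared regions where neither line's estimate sat at its genome-wide minimum. In the segment these were 611, 123 and 242 regions for GATA2, RUNX1 and SMC3. There the log2 ratio of Q592* to WT lay above that of the other chromosomes by 0.12, 0.16 and 0.29. The ratio of summit pileup per M reads, measured against the other chromosomes without this filter, went both ways (-0.14, -0.14 and 0.09). Without the filter, the median background of the segment was above that elsewhere in both lines. For GATA2 it was 1.89 and 1.51 times the genome-wide value in WT, 2.43 and 1.97 in Q592*. For RUNX1 the values were 2.18 and 1.79, then 3.01 and 2.42, and for SMC3 2.47 and 2.22, then 2.96 and 2.27. By these medians the segment stood apart by a similar factor in both lines for GATA2 and RUNX1. The rise in Q592* for these targets thus depends on how the background was compared. On 20q, beyond 30 Mb, the log2 ratio of Q592* to WT lay below that of the other chromosomes for pileup (differences of -0.15, -0.12 and -0.25, with ratios of 0.65, 0.53 and -0.14 on 20q) and for background (-0.29, -0.26 and -0.36), which would be in line with a lower copy number, although the ratio of peak counts on the whole of chromosome 20 (1.56, 1.83 and 0.80) was not below that of the full lists (1.515, 1.623 and 0.774). Chromosome 19, rich in genes, had nearly as low a background ratio (-0.22, -0.20 and -0.26), at least 0.05 above 20q, so by background alone a bias against gene-dense DNA cannot be told apart from copy number. Its pileup ratio differed less from that of the other chromosomes (-0.05, 0.04 and -0.07). This ratio lay above 20q by 0.10 (SE 0.029), 0.17 (SE 0.05) and 0.18 (SE 0.017), where the SE covers the spread between regions only. A bias of the background pools alone would not change the pileup of a given region, from which no background is subtracted. It could change which regions are called in both lines, so the pileup does not exclude such a bias. A bias shared by the ChIP reads also stays open. The gap is not beyond 0.1 by more than 2 SE in all 3 targets, although it is above 0 by that much. The 3 targets were measured in the same 2 lines and are not independent. A higher copy number of 13q in Q592* and biological explanations were not tested.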
